A study of Mus musculus with 5 samples.

How the data were processed

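Total RNA of sorted mouse cells was sequenced after library preparation with the Illumina TruSeq RNA kit, per the labels' protocols. A single table of 34240 features and 5 columns, one per library, was used, and each column was matched to its sample by the sample title. The deposited values are taken to be RPKM (reads per kilobase of exon, scaled to the mapped reads of each library) made by the authors, a unit that no label or header names. It was inferred because column totals ran from 472234 to 638584, and because values multiplied by exon length in kb summed to between 1058675 and 1124040 in every library. Steps between low values of 263 single-exon genes were whole multiples of 1 read, within rounding, for 100% of 73 values in normal library 1 (34.9% by chance), 98.4% of 124 in normal library 2 (70.2% by chance) and 95% of 20 in AML library 1 (38.1% by chance), at the best of a range of trial depths. The genome build was mm9, per the submitters' processing notes. Aligner, counting tool, annotation and filters are not given in the sources used here. No value was negative, and 16774 features were listed at 0 in every library.

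Values had been deposited with 0, 1 or 2 decimals depending on the feature, and all 11612 features with 0 decimals were 0 in every library. Among tested genes, 4749 had 1 decimal, of which 11.9% were higher in AML cells, with a highest log2 fold change of 0.60. A further 5417 had 2 decimals, of which 94.5% were higher in AML cells. The number of decimals thus largely follows the direction of change, and low values are coarser for genes that fell. Rounding every value to 1 decimal gave 1942 higher and 1174 lower genes.

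Groups were taken from the source labels: 3 normal and 2 AML libraries. The labels give no batch or date. The table held neither counts nor a column of another sample. Genes with at least 1 RPKM in at least 2 libraries were kept, which left 10166 genes. Values were transformed as log2(RPKM + 1), a scale that understates the change of low genes, and compared between AML and normal with limma 3.58.1 in R 4.3.3 (empirical Bayes with a variance trend and robust estimation, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Mean, SD and fold are of RPKM, and log2 fold changes and SE are from the limma fit. Among 25 gene lists with 373 entries (360 distinct genes), each with a tested member was tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera called 9 lists, 3 higher and 6 lower in AML cells, and none of them held with an estimated correlation (lowest adjusted p = 0.49). Fry called 5 lists: progenitor, primary granule, ribosome biogenesis, monocyte and macrophage, and T and NK cell. It did not call the mature neutrophil, plasmacytoid dendritic cell, inflammatory, erythroid and stress lists, which camera called. The estimated correlation was -0.03 for the primary granule list and -0.07 for the T and NK cell list, both below 0.01. Correlated genes were thus not why these 2 lists were lost. Estimates were higher for the other called lists: 0.88 (erythroid), 0.62 (stress), 0.57 (monocyte and macrophage) and 0.32 (plasmacytoid dendritic cell). They were 0.2 for the mature neutrophil, 0.12 for the inflammatory and 0.1 for the ribosome biogenesis list. The preset of 0.01 lies below all of these, so camera p-values at the preset can be too small for those lists. With an estimated correlation camera rests on the few degrees of freedom that 5 libraries leave, so it can miss a list for that reason alone. Fry tests whether a list's genes move one way on balance and compares them with no other genes. Older gene symbols were matched through synonyms in a RefSeq table.

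The groups, the test, the filter, the lists and the rule for naming genes were fixed before the data were examined. That rule took Fgfr1 and centriolin, the 5 genes of the sorting antigens, and the 6 largest rises and 6 largest falls among called genes with groups that did not overlap and a mean above 9.76 RPKM, the median of tested genes. From each list it took the 3 or 2 called members with the largest change, or the member with the highest mean where none was called. This gave 65 genes. Other genes are named where a count was small or where levels in single libraries are given, and were chosen after their values were seen.

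Coordinates and Ensembl identifiers came from the GENCODE M1 annotation of the mm9 assembly, matched by symbol for 9934 of the tested genes. Where features carried coordinates of their own, 40 of 42 overlapped the annotated gene. Transcript length and GC content were known for 9876 tested genes (97.1%). Identifiers of genes named first are ENSMUSG00000031565 for Fgfr1, ENSMUSG00000057110 for centriolin, ENSMUSG00000042817 for Flt3, ENSMUSG00000032093 for Cd3e and ENSMUSG00000020125 for Elane.

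Alternatives fixed beforehand were upper quartile scaling, no filter, a filter at 5 RPKM, a pseudocount of 0.1, no variance trend, an absolute log2 fold change of at least 1, an adjusted p under 0.01, leaving out each library in turn, an estimated correlation for lists and Spearman's correlation for similarity. Alternatives added after seeing the data were removal of per-library smooth trends with transcript length, GC content or both (mgcv 1.9.3), quantile normalization, rounding to 1 decimal, and leaving out both normal libraries 1 and 2. After the data were seen, 8 gene families defined by symbol stems were also tested with camera, adjusted among themselves. Count-based tests and scalings among the alternatives were not run because the table holds RPKM.

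The fit was tested on simulated data for AML against normal over 10166 genes. It recovered 88% of 50 genes changed by 3 on the log2 scale, 54% of 50 changed by 2, and 0% of those changed by 1 or 0.5, with 4 calls among 9966 unchanged genes. SDs were shuffled between genes. With so few changed genes the adjusted threshold was stricter than in the data, where 3155 genes were called, among them Oas1a (-0.80) and Gp9 (0.81). These shares therefore do not carry over to the data. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.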

Results

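RNA sequencing values were compared between 5 libraries from BALB/c mice whose age the labels give as 10 to 12 months. Normal myeloid cells carrying the surface antigens Gr1 and Mac1 had been sorted from bone marrow and gave 3 libraries. Cells of an acute myeloid leukaemia (AML) had been sorted for Mac, Gr1 and B220 and gave 2 libraries, with bone marrow and spleen as their tissue. The leukaemia was induced by CNTRL-FGFR1, a fusion of the centrosomal protein centriolin with the receptor tyrosine kinase FGFR1. The design addresses how gene expression in the sorted leukaemia cells differs from that in normal myeloid cells. Spleen was part of the tissue, and B220 part of the sort, in the AML group alone. Neither tissue nor sort can therefore be told apart from group. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which can be technical. The deposited table held RPKM values, not counts, so no total count per library can be given. RPKM totals were 472234, 529058 and 615921 in normal libraries 1 to 3 and 524000 and 638584 in AML libraries 1 and 2. The steps between low values gave a depth near 33000000 reads for normal library 1, 75000000 for normal library 2 and, from 20 values only, 35750000 for AML library 1, each the best of a range of trial depths. Depth could not be recovered for the other two libraries. The calprotectin genes S100a8 and S100a9, abundant in neutrophils, made up 28.1%, 32.8% and 37.0% of the RPKM total in the normal libraries and 20.8% and 30.1% in the AML libraries.

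The mouse genes of the 2 fusion partners were compared first. Mouse Fgfr1 (chromosome 8, 26624126 to 26686186, mm9) was listed at 0.0233 ± 0.0058 RPKM (SD, n = 3) in normal cells and 0.155 ± 0.0071 RPKM (SD, n = 2) in AML cells, a ratio of means of 6.64. These levels lay under the filter of 1 RPKM. At the depths above they corresponded to about 5 reads in normal library 1, 18 in normal library 2 and 43 in AML library 1. With no filter on low values the log2 fold change of Fgfr1 on the log2(RPKM + 1) scale was 0.17 (SE 0.02, limma, Benjamini-Hochberg adjusted p = 0.0099). The centriolin gene, listed as Cep110 (chromosome 2, 34965012 to 35034342), stood at 33.6 ± 2.03 RPKM (SD, n = 3) and 44.3 ± 3.32 RPKM (SD, n = 2). Its log2 fold change of 0.39 (SE 0.22) did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.21). A value per gene does not separate fusion transcripts from those of the endogenous genes, and the species of the FGFR1 part of the fusion is not given in the sources used here.

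The genes of the sorting antigens were all transcribed in both groups, and Itgam, Ly6g and Ptprc fell in AML cells. Itgam, which encodes the Mac1 alpha chain, was 2.33-fold lower, at 489 ± 80.5 RPKM (SD, n = 3) in normal and 209.95 ± 57.9 RPKM (SD, n = 2) in AML cells. Ly6g, which encodes part of the Gr1 epitope, was 2.31-fold lower (log2 fold change -1.22, SE 0.29). Ptprc, whose B220 isoform was a sorting marker of the AML cells alone, was 3.05-fold lower at the level of the whole gene (228 ± 55.9 against 74.7 ± 4.24 RPKM, SD). Adjusted p-values were 0.02 for Itgam, 0.02 for Ly6g and 0.0087 for Ptprc (limma, Benjamini-Hochberg). Ly6c1 and Ly6c2, near-identical neighbours whose reads can be split between them, had log2 fold changes of 0.21 (SE 0.36, adjusted p = 0.68) and 0.70 (SE 0.27, adjusted p = 0.093). The call of Itgam was lost without normal library 1, normal library 2 or AML library 2 (adjusted p up to 0.15) and that of Ly6g without any one of those or AML library 1 (up to 0.14). That of Ptprc was lost without either AML library (up to 0.069), and the sign of Ly6c1 turned without normal library 3 (-0.06) or AML library 1 (-0.055), under quantile normalization (-0.12) and with the length trend removed (-0.26).

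Across 10166 tested genes, 1959 were higher and 1196 lower in AML cells than in normal myeloid cells (limma, Benjamini-Hochberg adjusted p under 0.05). Of the 7 stefin A genes 6 were, with Cd3e, Flt3 and Elane, among the rises above 5 on the log2 scale, and Chi3l1 and Fn1 fell by more than that. Pearson correlations of log2(RPKM + 1) averaged 0.955 (SD 0.027) between libraries of one group and 0.821 (SD 0.038) between groups, and the lowest within-group value, 0.924, exceeded the highest between-group value, 0.857. Normal libraries 1 and 2 correlated at 0.988, while normal library 3 correlated at 0.924 and 0.944 with them. The first principal component held 75.9% of the variance and placed the normal libraries at -53.9, -46.6 and -23 and the AML libraries at 53.2 and 70.4. The second held 17.6% and set normal library 3 (-43.7) apart from normal libraries 1 and 2 (19.6 and 10.5). Leaving out one library gave 1139 higher and 797 lower genes without normal library 1, 955 and 640 without normal library 2, 2757 and 2142 without normal library 3, 693 and 605 without AML library 1, and 326 and 348 without AML library 2. Without both normal libraries 1 and 2 there were 864 higher and 471 lower genes, with the spread taken from the 2 AML libraries and normal library 3 assumed to vary like them.

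Of the 6 largest rises named here 5 were in cystatin-type protease inhibitors of the stefin A family, and the 6 largest falls were those of Chi3l1, Fn1, Mmp25, Ctsh, Il1b and Ear2. BC100530, listed with the second name Stfa1, stood at 81 ± 25.9 RPKM (SD, n = 3) in normal and 15408 ± 8227 RPKM (SD, n = 2) in AML cells, a log2 fold change of 7.49 (SE 0.44). Gm5483 (6.99, SE 0.53), Stfa2 (6.57, SE 0.52), BC117090 (6.29, SE 0.26) and Stfa3 (6.05, SE 0.40) rose with it. Stefin A genes are near-identical copies clustered on chromosome 16, where Stfa2 lies at 36404037 to 36421006 and Stfa3 at 36450623 to 36455478, so reads can be split between them. Cd3e, a chain of the T cell receptor complex on chromosome 9 (44806826 to 44817673), rose from 0.317 ± 0.211 RPKM (SD, n = 3) to 219 ± 19.6 RPKM (SD, n = 2), a log2 fold change of 7.39 (SE 0.23). Chi3l1, a chitinase-like protein, was 35.7-fold lower (480.03 ± 82.6 against 13.5 ± 2.47 RPKM, SD). Fn1, fibronectin, was 41.2-fold lower, Mmp25, a membrane-bound matrix metalloproteinase of neutrophils, 42.8-fold and Ctsh, cathepsin H, 22.9-fold. Il1b and Ear2 were 30.5-fold and 28.6-fold lower. Adjusted p-values of these 12 genes ranged from 8.5e-05 for Cd3e to 0.0041 for Ear2 (limma, Benjamini-Hochberg). Each passed in every fit without one library that tested it. Cd3e fell under the filter without either AML library and was not tested there.

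**Figure D1:**
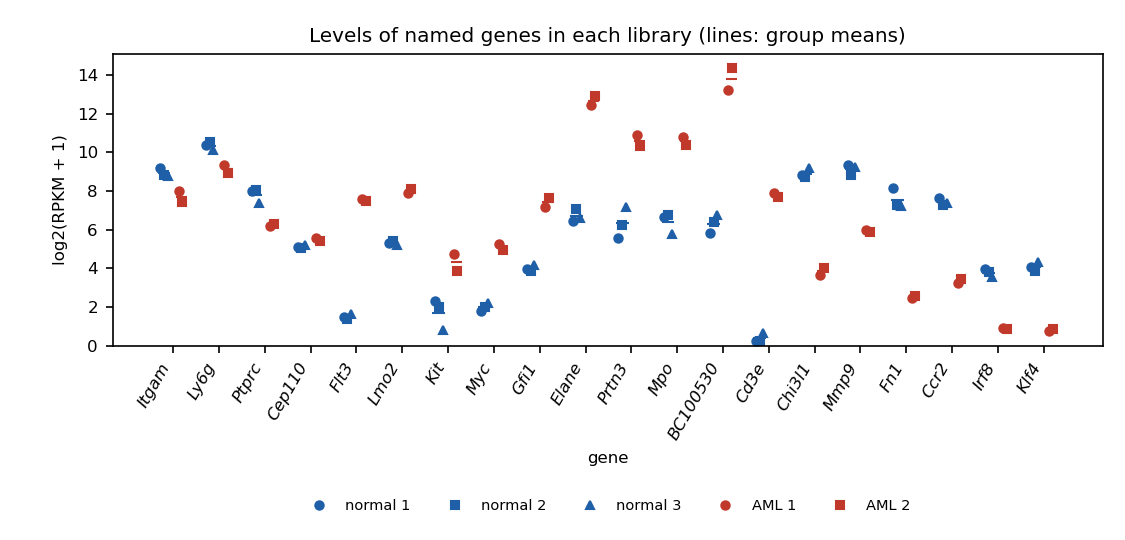
Level of 20 named genes in each library, as log2(RPKM + 1); blue symbols are the 3 normal libraries, red symbols the 2 AML libraries, and short lines the group means. The AML libraries sit at 187.45 and 175.88 RPKM for Flt3, against 1.56 to 2.09 RPKM in normal libraries.

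Stem and progenitor cell genes moved in both directions, and 6 of 7 primary granule genes rose. Of 11 tested progenitor genes 5 rose, namely Flt3, Lmo2, Kit, Myb and Cdk6, and 3 fell, namely Pbx3, Tal1 and Cd34. Adjusted over the list alone, 6 rose and 4 fell. Flt3, a receptor tyrosine kinase of early progenitors, went from 1.82 ± 0.265 RPKM (SD, n = 3) to 182 ± 8.18 RPKM (SD, n = 2), a 99.8-fold difference (log2 fold change 6.02, SE 0.21, limma adjusted p = 9.2e-05). Lmo2, a haematopoietic transcription cofactor, was 6.57-fold higher and Kit, the stem cell factor receptor, 7.69-fold higher. The progenitor list as a whole did not pass with camera (limma camera, Benjamini-Hochberg adjusted p = 0.35), while fry called it (Benjamini-Hochberg adjusted p = 0.036). Hoxa9 and Meis1, homeobox genes of many leukaemias, were listed at 0 in both AML libraries. All 7 primary granule genes passed the test, 6 higher and 1 lower, with the same numbers adjusted over the list alone. Elane, neutrophil elastase, rose 62.2-fold to 6543 ± 1466 RPKM (SD, n = 2), Prtn3, proteinase 3, 17.9-fold, and Mpo, myeloperoxidase, 17.8-fold. Ctsc, the dipeptidyl peptidase that activates granule proteases, fell 8.51-fold. This list passed with a median log2 fold change of 3.59 (limma camera, Benjamini-Hochberg adjusted p = 0.004; adjusted p = 0.49 with an estimated correlation). The call of Kit was lost without AML library 1, where its log2 fold change was 2.16. Without both normal libraries 1 and 2 the progenitor median was 2.77, over 7 of the 11 genes. Pbx3, Tal1 and Cd34, which fell, were under the filter there, as was Hlf. That median is thus no support for a rise of the list as a whole.

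Genes of later neutrophil stages and of monocytes were mostly lower or did not pass the test. Among 18 secondary and tertiary granule genes, Fcnb, Orm1 and Cebpe rose and Mmp9, Mmp8 and Ltf fell, and the counts adjusted over the list alone were also 3 and 3. Mmp9, gelatinase B, was 9.31-fold lower and Mmp8, neutrophil collagenase, 6.85-fold lower (1447 ± 124 against 211 ± 48.6 RPKM, SD), while Fcnb, ficolin B, was 3.87-fold higher. The median of this list was -0.13 (limma camera, Benjamini-Hochberg adjusted p = 0.37). Of 21 receptors and effectors of mature neutrophils 2 rose, both stefin A genes (BC100530 and Stfa2l1), and 9 fell, and adjusted over the list alone 3 rose and 9 fell. Clec4d, a C-type lectin receptor, was 19.3-fold lower. The list passed in the lower direction with a median of -1.17 (limma camera, Benjamini-Hochberg adjusted p = 0.0046; adjusted p = 0.70 with an estimated correlation). Monocyte and macrophage genes gave the lowest median of all lists, -2.38, with 8 of 14 lower, none higher, and 9 lower adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 9.7e-06; adjusted p = 0.70 with an estimated correlation). This list also differed within the normal group, with a median log2 difference of -0.96 for normal library 3 against normal libraries 1 and 2. Without both of those the median between the groups was -2.48, over the 12 genes tested there. Fn1 and Ccr2, the chemokine receptor of inflammatory monocytes, fell most on the log2(RPKM + 1) scale, Ccr2 by 18.5-fold in RPKM (170.2 ± 21.2 against 9.2 ± 0.849 RPKM, SD). Fry did not call the mature neutrophil list (Benjamini-Hochberg adjusted p = 0.22). Its call by camera was lost without AML library 1 (adjusted p = 0.066), and the median of late granule genes turned to 0.10 without normal library 3. The late granule list passed with length and GC trends removed (median -0.50, adjusted p = 0.037; 0.58 with an estimated correlation) and without both normal libraries 1 and 2 (median -0.47, adjusted p = 0.0048; 0.56 with an estimated correlation).

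Of the ribosome biogenesis genes 11 rose in AML cells, and cell cycle genes moved in both directions. Among 24 cell cycle genes 9 were higher and 2 lower (10 and 2 adjusted over the list alone). Mcm7, Mcm2 and Mcm3, subunits of the replicative helicase, were 3.77-fold, 3.80-fold and 3.26-fold higher, with log2 fold changes of 1.90 (SE 0.31), 1.82 (SE 0.31) and 1.61 (SE 0.28). The lower genes were the cyclins Ccna2 and Ccnb1, and the list did not pass (median 0.25, limma camera, Benjamini-Hochberg adjusted p = 0.37). Of 20 ribosome biogenesis and MYC-responsive genes 11 rose and none fell, or 13 adjusted over the list alone. Ppan and Nop56, factors of ribosomal subunit assembly, were 4.35-fold and 3.39-fold higher. This list passed with a median of 0.82 (limma camera, Benjamini-Hochberg adjusted p = 0.0023; adjusted p = 0.60 with an estimated correlation). Calls of Ppan and Nop56 were lost without AML library 2 (adjusted p = 0.11 and 0.068) and that of Mcm7 without AML library 1 (0.051).

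**Figure D2:**
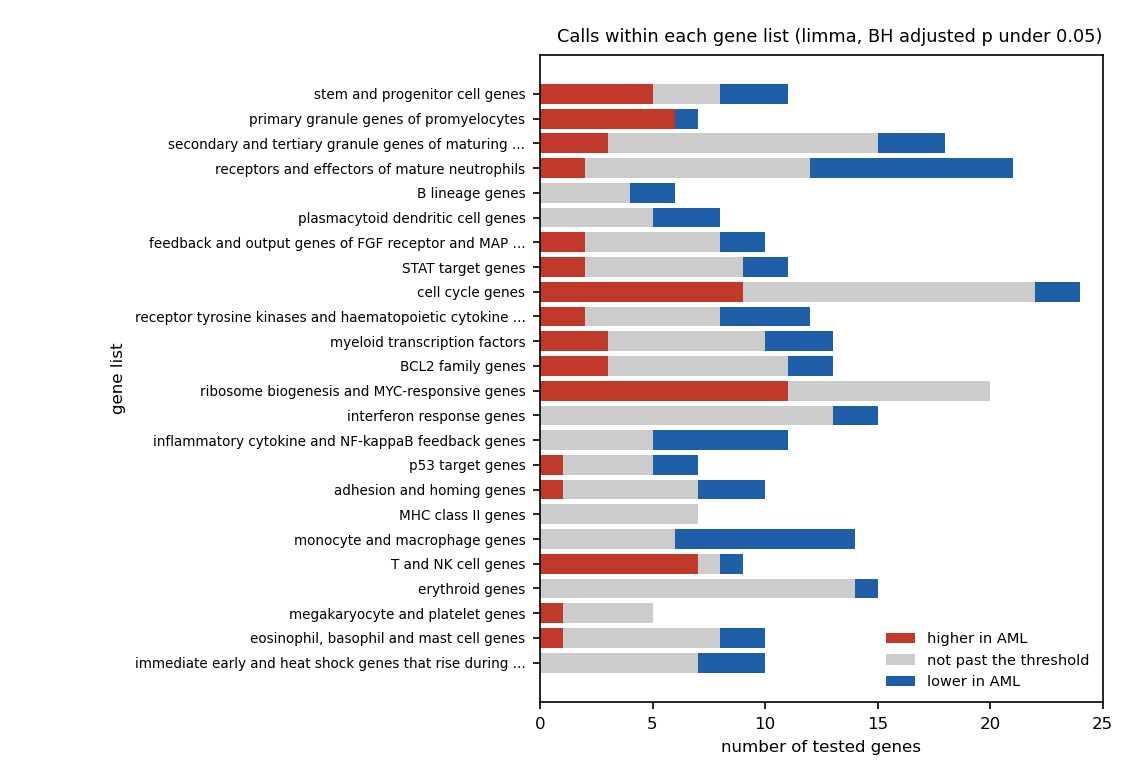
Number of tested genes in each of the 24 lists with a tested member (horizontal axis) that were higher (red), lower (blue) or not past the threshold (grey) in AML against normal cells. Primary granule, T and NK cell and ribosome biogenesis lists hold mostly red or grey, and monocyte and macrophage and inflammatory lists hold blue and grey.

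Signalling and transcription factor genes moved both ways within each list, and none of these lists passed. Among 10 feedback and output genes of FGF receptor and MAP kinase signalling Spry1 and Spry2 rose and Egr1 and Dusp5 fell (2 and 3 adjusted over the list alone; median -0.51, limma camera, Benjamini-Hochberg adjusted p = 0.35). Spry1, a feedback inhibitor of receptor tyrosine kinases, went from 0.13 ± 0.036 to 3 ± 0.24 RPKM (SD), a log2 fold change of 1.82 (SE 0.17). Of 11 STAT target genes Myc and Cish rose and Osm and Bcl6 fell, also 2 and 2 adjusted over the list alone (median -0.22, camera adjusted p = 0.57). Myc, a growth-promoting transcription factor on chromosome 15 (61816946 to 61821929), was 11-fold higher (3.01 ± 0.54 against 33 ± 5.32 RPKM, SD; adjusted p = 0.00039), and Cish, a suppressor of cytokine signalling, 5.59-fold higher. Of 12 receptor tyrosine kinases and cytokine receptors Flt3 and Kit rose and Csf1r, Il6ra, Met and Csf3r fell, with the same calls adjusted over the list alone (median -0.45, camera adjusted p = 0.24). Csf1r, the macrophage colony-stimulating factor receptor, was 11.3-fold lower. Among 13 myeloid transcription factors Gfi1, Cebpa and Cebpe rose and Klf4, Irf8 and Klf2 fell, again 3 and 3 adjusted over the list alone (median -0.01, camera adjusted p = 0.63). Gfi1, a repressor needed for granulocyte formation, was 11.3-fold higher and Klf4, a factor of monocyte formation, 21.4-fold lower. The median of the transcription factor list was above 0 without any one normal library or AML library 1 (up to 0.20), and the STAT list passed without both normal libraries 1 and 2 with normal library 3 alone for its group (median -0.41, adjusted p = 0.00078; 0.56 with an estimated correlation). Calls lost without at least one library were those of Egr1 (either AML library, adjusted p up to 0.12), Cish (either AML library, up to 0.088), Osm (normal library 2 or either AML library, up to 0.19) and Dusp5 (each but normal library 3, up to 0.25).

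Only 6 of 19 B lineage genes reached the filter although B220 was a sorting marker of the AML cells, while 7 of 9 tested T and NK cell genes rose. Of these 6 B lineage genes Vpreb3 and Cd72 fell, as also adjusted over the list alone (median -0.25, limma camera, Benjamini-Hochberg adjusted p = 0.13). Among 8 plasmacytoid dendritic cell genes Irf8, Ly6d and Spib fell and none rose, also adjusted over the list alone, with a median of -0.95 (camera adjusted p = 0.027; adjusted p = 0.70 with an estimated correlation). Fry did not call the plasmacytoid list (Benjamini-Hochberg adjusted p = 0.078). Irf8, a transcription factor of monocytes and dendritic cells, was 15.1-fold lower. In the T and NK cell list Cd3e, Cd3g, Nkg7, Lat, Tcf7, Thy1 and Gzma rose and Cd3d fell, also 7 and 1 adjusted over the list alone (median 1.73, camera adjusted p = 0.0037; adjusted p = 0.49 with an estimated correlation). Cd3g, a further chain of the T cell receptor complex, rose 85.8-fold, to 102 ± 17.3 RPKM (SD, n = 2), whereas Cd3d fell 2.49-fold and Cd2 and Lck stayed under 1 RPKM in every library. All 7 tested MHC class II genes missed the threshold, also adjusted over the list alone (median -0.75, camera adjusted p = 0.093), with Cd74, the invariant chain, at 71.8 ± 41.6 and 27.8 ± 4.17 RPKM (SD). The plasmacytoid call was lost without normal library 1 (adjusted p = 0.057), normal library 2 (0.051) or AML library 1 (0.14) and the T and NK call without AML library 1 (0.066), while MHC class II genes passed without normal library 3 (0.013; 0.57 with an estimated correlation) or AML library 2 (0.039; 0.65). Without both normal libraries 1 and 2 the medians were 0.08 for plasmacytoid dendritic cell genes, 0.05 for B lineage genes and 0.04 for MHC class II genes. Only 4 genes of each of the first 2 lists reached the filter there. Irf8, Ly6d, Spib, Vpreb3 and Cd72, all called lower, were not among them, so these 2 medians cannot show that the fall was absent. Irf8 stood at 10.5 RPKM in normal library 3 and at 0.9 and 0.8 RPKM in the AML libraries. Calls of Vpreb3 (adjusted p up to 0.086), Cd72 (0.11) and Ly6d (0.068) were lost without either AML library and that of Spib also without normal library 2 (up to 0.13), and Cd74 passed without normal library 3.

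With camera the inflammatory and stress lists passed in the lower direction, and the interferon, p53, BCL2 family and adhesion lists did not pass. Fry called none of these lists (Benjamini-Hochberg adjusted p = 0.08 for the inflammatory and 0.39 for the stress list). Of 11 inflammatory cytokine and NF-kappaB feedback genes 6 fell and none rose, with the same numbers adjusted over the list alone (median -1.82, limma camera, Benjamini-Hochberg adjusted p = 0.004; adjusted p = 0.60 with an estimated correlation). Il1b, interleukin 1 beta, fell from 166 ± 119 to 5.44 ± 2.11 RPKM (SD) and Nlrp3, an inflammasome sensor, fell 18-fold. Immediate early and heat shock genes, which also respond to cell handling, had Atf3, Egr1 and Fosb lower among 10, or 4 lower adjusted over the list alone (median -1.34, camera adjusted p = 0.015; adjusted p = 0.70 with an estimated correlation). The median of that list was 1.82 higher on the log2 scale in normal library 3 than in normal libraries 1 and 2. Gbp2 and Oas1a were the only 2 of 15 interferon response genes to fall, with none higher, also adjusted over the list alone (median -0.53, camera adjusted p = 0.056). Of 7 p53 targets Bax rose and Sesn2 and Trp53inp1 fell, also adjusted over the list alone (median -0.52, camera adjusted p = 0.37). Of 13 BCL2 family genes Bax, Bcl2l2 and Bcl2a1a rose and Pmaip1 and Mcl1 fell, also adjusted over the list alone. Mcl1, a survival factor of granulocytes, was 3.17-fold lower. The BCL2 family median was 0.27 and its mean -0.01 (camera, direction up, adjusted p = 0.93). Among 10 adhesion and homing genes Itga5, an integrin chain, rose 4.25-fold, while Cd44, Itgb1 and Selplg fell, also adjusted over the list alone (median -0.57, camera adjusted p = 0.11). The inflammatory call was lost without AML library 1 (adjusted p = 0.066) and the stress call without normal library 3 (0.10) or AML library 1 (0.16), while interferon genes passed without normal library 3 (0.0086) or AML library 2 (0.0093) and adhesion genes without normal library 3 (0.024), none of them with an estimated correlation (0.57 to 0.65). In normal library 3 the interferon median was 1.09 lower than in normal libraries 1 and 2, and without both of those it was -0.10 between the groups (adjusted p = 0.9), with 2 genes higher and 0 lower. The adhesion median was 0.14 and the p53 target median 0.05 in that setting (adjusted p = 0.77 and 0.4). Calls of Gbp2 (adjusted p up to 0.19), Oas1a (0.15), Bax (0.18) and Pmaip1 (0.18) were lost without any one library but normal library 3, those of Atf3 (0.11) and Itga5 (0.12) without either AML library, that of Mcl1 (0.12) without normal library 2 or either AML library, that of Cd44 (0.11) without normal library 2 or AML library 2, and that of Sesn2 (0.054) without AML library 2.

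Markers of other blood lineages differed between the normal libraries as well as between the groups. Erythroid genes were 1 lower (Car1, carbonic anhydrase 1, by 13.9-fold) and none higher of 15, also adjusted over the list alone, with a median of -1.21 (limma camera, Benjamini-Hochberg adjusted p = 0.004; adjusted p = 0.70 with an estimated correlation). Fry did not call the erythroid list (Benjamini-Hochberg adjusted p = 0.39). Hba-a1, an alpha globin gene with a near-identical copy that can share its reads, was listed at 1332, 855.9 and 87.4 RPKM in normal libraries 1 to 3 and at 97.7 and 109.5 RPKM in the AML libraries. Of 10 eosinophil, basophil and mast cell genes Siglec5 rose and Ear2 and Prss34 fell, also adjusted over the list alone (median -0.91, camera adjusted p = 0.13). Prg2, eosinophil major basic protein, was listed at 584.3, 603.6 and 3.8 RPKM in normal libraries 1 to 3 and at 87.5 and 184.8 RPKM in the AML libraries. Prss34, a basophil and mast cell protease, was 17-fold lower in AML cells (log2 fold change -2.96, SE 0.22). Of 5 megakaryocyte and platelet genes Gp9 rose, also adjusted over the list alone (median -0.56, camera adjusted p = 0.42), and that call was lost with length and GC trends removed (log2 fold change 0.06, adjusted p = 0.90) or without normal library 2 (0.062). None of the 8 stromal and endothelial genes reached the filter. Without both normal libraries 1 and 2 the erythroid median was 0.33 over 9 of the 15 genes, as the others were under the filter. The eosinophil, basophil and mast cell median was 1.66 over 8 of the 10 genes, without Prss34, which was under the filter too. The erythroid call was also lost without AML library 1 (0.066), and the eosinophil, basophil and mast cell list passed in the lower direction without normal library 3 (0.0016; 0.57 with an estimated correlation) or AML library 2 (0.047; 0.65).

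**Figure D3:**
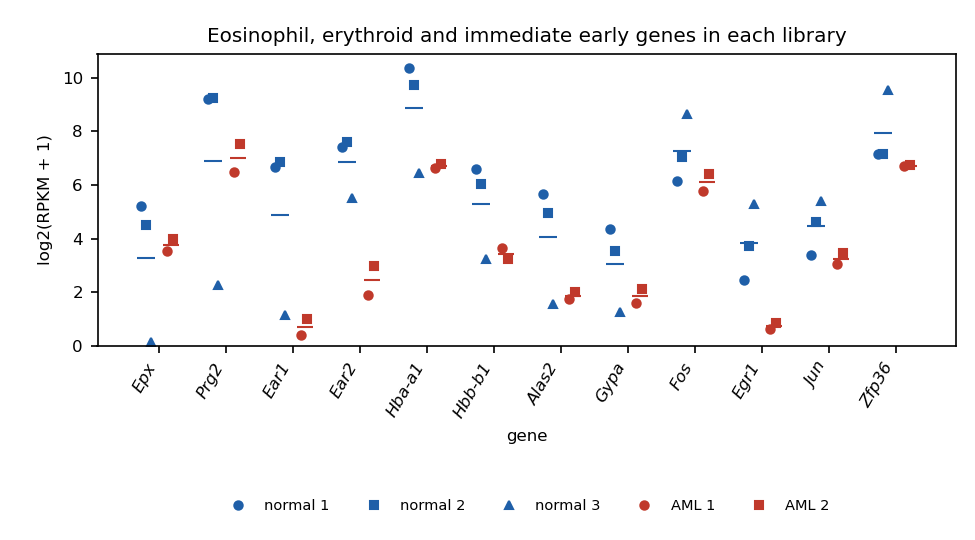
Level of 12 eosinophil, erythroid and immediate early genes in each library, as log2(RPKM + 1); blue symbols are the 3 normal libraries, red symbols the 2 AML libraries, and short lines the group means. Prg2 and Hba-a1 are lowest in normal library 3 (3.8 and 87.4 RPKM), where Fos is highest.

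Genes with short transcripts tended to be higher in AML cells and those with long transcripts lower. The median log2 fold change fell from 0.60 among 988 genes with transcripts of 291 to 1188 nt to -0.32 among 988 genes with transcripts of 6029 to 28204 nt, and Spearman's rho across 9876 genes was -0.29 with length and 0.24 with GC content. Genes are not independent replicates, so no p-value is given for these. Trends with length also separated libraries within groups, with rho of -0.46 for normal library 3 against normal libraries 1 and 2, -0.48 for normal library 2 against 1, and -0.38 for AML library 2 against 1. With GC content rho was 0.36, -0.22 and 0.16 in the same order. The sign within a group depends on which library is subtracted. With both trends removed 2133 genes were higher and 1309 lower, of which 1626 and 1044 were shared with the original calls. Flt3 (log2 fold change 6.15), Elane (5.30), Myc (3.02) and Ccr2 (-3.58) passed the test with both trends removed.

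**Figure D4:**
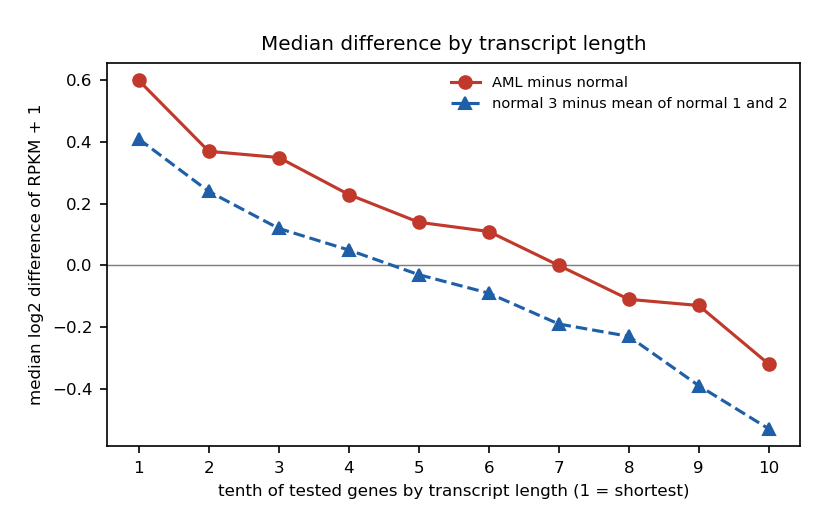
Median log2 difference of RPKM + 1 (vertical axis) in 10 equal groups of the tested genes ordered by transcript length (horizontal axis, 1 shortest), for AML against normal cells (red) and for normal library 3 against normal libraries 1 and 2 (blue). The AML difference falls from 0.60 to -0.32 and the difference within the normal group from 0.41 to -0.53.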

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

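Tests with trends removed, quantile normalization, rounding and removal of both normal libraries 1 and 2 were chosen after seeing the data. Of 60 named genes called, 35 were lost in no fit without one library and 25 were lost at least once, and no called gene turned its sign. Only 57 of the 60 reached the filter without either AML library. Cd3e, Spry1 and Gp9 were not tested there, and Cd3e and Spry1 are among the 35. Counts were 802 higher and 541 lower at an adjusted p under 0.01, 864 and 471 without both normal libraries 1 and 2, and 326 to 2757 higher and 348 to 2142 lower when one library was left out, where fewer samples enter and a lone AML or normal library is assumed to vary like those of the other group. Under upper quartile scaling, no filter, the stricter filter, a pseudocount of 0.1, no variance trend, a minimum log2 fold change of 1, trend removal, quantile normalization and rounding both counts stayed within 1.5 times. The number of lists called, 9, was 3 to 12 when one library was left out and 0 with an estimated correlation, under which no list passed in any setting (lowest adjusted p = 0.32, upper quartile scaling). The difference between correlations within and between groups, 0.134, was 0.057 with no filter and 0.107 to 0.175 with one library left out. Ly6c1 had a log2 fold change of -0.26 with the length trend removed, -0.20 with length and GC trends removed, -0.124 under quantile normalization and -0.06 to 0.474 with one library left out. List medians whose sign turned without both normal libraries 1 and 2 were 0.052 (B lineage), 0.08 (plasmacytoid dendritic cell), 0.266 (myeloid transcription factors), 0.046 (p53 targets), 0.136 (adhesion), 0.042 (MHC class II), 0.325 (erythroid), 0.27 (megakaryocyte) and 1.659 (eosinophil, basophil and mast cell). Others were -0.074 for progenitor genes with no filter, -0.57 for BCL2 family genes with the stricter filter, and, with one library left out, from -0.30 to 0.096 for late granule genes, from -0.039 to 0.201 for myeloid transcription factors and from -1.20 to 0.007 for megakaryocyte genes. Without both normal libraries 1 and 2, genes under 1 RPKM in both AML libraries fell under the filter. Medians there cover 4 of 6 B lineage, 4 of 8 plasmacytoid dendritic cell and 11 of 13 transcription factor genes. They cover 9 of 15 erythroid, 2 of 5 megakaryocyte and 8 of 10 eosinophil, basophil and mast cell genes. Lists that passed under another setting, besides those given with the results, included progenitor (camera adjusted p = 0.0048) with the stricter filter, B lineage (0.0091) with no filter, and late granule (0.037), interferon (0.040) and MHC class II (0.037) with both trends removed. Pbx3, Tal1 and Cd34, the progenitor genes that fell, did not reach the stricter filter and were not tested with it. Calls lost included plasmacytoid dendritic cell (0.24) and erythroid (0.053) with the stricter filter and T and NK cell (0.076) and stress (0.076) with no filter. Except where fewer genes or samples enter, the cause was not tested. No paired analysis was possible because the groups share at most 1 number in their sample titles, and no label ties it to an animal, litter or batch. Count-based alternatives (size factors, library size alone, a count test and voom) were not run. Depth is unknown for normal library 3 and AML library 2. None of 50 simulated changes of 1 on the log2 scale was recovered, with 9966 of 10166 genes unchanged. The adjusted threshold was less strict in the data, where 3155 genes were called, so that share does not carry over.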

Other observations

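The tests of trends, cell types, locus and gene families below were chosen only after the result was seen, and the count of splits was planned. In all, 8 families were tested, and each is given here. Cytosolic ribosomal protein genes, which encode the parts of the ribosome and have many processed pseudogenes that can share their reads, were mostly higher in AML cells: 70 of 81 tested genes were higher and none lower (limma, Benjamini-Hochberg), with a median log2 fold change of 1.59 (camera adjusted p = 8.2e-18; adjusted p = 0.45 with an estimated correlation). The median was 1.49 under upper quartile scaling, 1.41 under quantile normalization and 1.04 with length and GC trends removed, where 59 of 80 genes were higher. Without AML library 2, 14 were higher, and without AML library 1, normal library 2 or normal library 1 there were 38, 48 and 60, and 39 without both normal libraries 1 and 2 (median 1.26). All 7 stefin A genes were higher, with a median log2 fold change of 6.29 that was 6.19 and 6.02 under the scalings.

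Mitochondrial ribosomal protein genes had 21 of 76 higher, none lower and a median of 0.62 (camera adjusted p = 5.8e-06; 0.69 with an estimated correlation). That median was 0.35 with trends removed (camera adjusted p = 0.024, or 0.38 with an estimated correlation). Its value was 0.38 without both normal libraries 1 and 2. Respiratory complex I subunit genes had 5 of 36 higher, none lower and a median of 0.62 (camera adjusted p = 0.0024; 0.76 with an estimated correlation), which was 0.16 with trends removed (adjusted p = 0.35) and also without both normal libraries 1 and 2, where 0 were higher. Leaving out one library moved the number higher from 0 without AML library 2 to 44 and 23 without normal library 3 in these 2 families. Camera did not call the other 4 families. Proteasome subunit genes had 6 of 38 higher and a median of 0.22 (adjusted p = 0.28), which was 0.03 with trends removed and -0.03 without both normal libraries 1 and 2. Zinc finger protein genes had 27 higher and 13 lower of 205 and a median of 0.03 (adjusted p = 0.63), which was -0.04 under upper quartile scaling and 0.21 with trends removed, where 41 of 202 were higher. Chaperonin CCT genes had 1 of 6 higher and a median of 0.37 (adjusted p = 0.28), which was 0.02 to 0.72 with one library left out. C-type lectin genes had 4 higher and 7 lower of 20 and a median of -0.39 (adjusted p = 0.083), which was -0.01 without both normal libraries 1 and 2. The number higher without AML library 2 and without normal library 3 was 1 and 9 for proteasome subunit genes, 2 and 38 for zinc finger protein genes, and 1 and 6 for C-type lectin genes.

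The number of genes that differed between AML and normal was set against all 10 splits of the libraries into 3 and 2. Only the real split, 1 of 10, gave as many genes, with 3155 against 14 for the highest of the others, which set normal libraries 1 and 2 against the rest. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes AML and normal libraries in a group, so the difference between them widens its spread and lowers its count. The gap between 3155 and 14 is thus no measure of chance.

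Short transcripts were higher and long transcripts lower in AML cells. That length and GC trends were the whole cause of the calls is argued against, since 87.9% of the calls (2670 of 3037 with a known length) were kept with both trends removed. A length bias that differs between libraries may account for part of the trend itself, because normal library 3 differed from normal libraries 1 and 2 with a rho of -0.46, within one group. The biological difference between the groups stays open as a further source and was not tested.

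Genes of the erythroid list and of the eosinophil, basophil and mast cell list were higher in normal libraries 1 and 2 than in normal library 3. Of 25 members with a mean of at least 1 RPKM, 22 (88%) were at least 2-fold lower in normal library 3, with a median ratio of 9.51. The basophil and mast cell genes Prss34 and Mcpt8 and the erythroid gene Car1 were not. Ccr3 reached that mean only through normal libraries 1 and 2 (3.1 and 3.0 RPKM, 0.2 elsewhere), so the filter itself favours such genes. The median difference was -1.93 with length and GC trends removed. Medians by transcript length ran only from 0.41 to -0.53 between these libraries, so the length trend is too small to give that difference. Eosinophils and erythroid cells in the sorted fraction may be the source, with Hba-a1 at 1332 and Prg2 at 584.3 RPKM in normal library 1. A sort on Gr1 and Mac1 would remove erythroid cells, which lack these antigens, while eosinophils carry Mac1. No biological difference between the normal libraries is given by the labels, so none was tested.

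Cd3e, which ranked 2 among all tested genes by log2 fold change, and Cd3g rose in AML cells, as did Nkg7 (to 252 RPKM). Lat, Tcf7, Thy1 and Gzma also rose, at lower levels (9.4, 3.845, 4.105 and 4.78 RPKM). T cells in the sorted fraction are argued against, because the highest of Cd2, Lck, Zap70, Cd247 and Cd8a reached 0.25% of the Cd3e level (Cd247, 0.55 RPKM). Median log2 fold changes by transcript length ran only from 0.60 to -0.32, so the length trend is too small to give the rise of Cd3e. With length and GC trends removed the log2 fold change of Cd3e was 7.18. Trends that small could hardly have removed the rise, so this test adds little. A rise of all genes around the locus is argued against, since 0 of 5 other tested genes within 100 kb were higher, and Cd3d, which lies between Cd3g and Cd3e, fell by 1.26 on the log2 scale. Transcription of Cd3e and Cd3g in the leukaemia cells themselves stays open and was not tested.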
